A study of Mus musculus with 8 samples.

How the data were processed

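Gene expression was measured on 8 Affymetrix arrays, each hybridised with RNA from pancreatic islets of NOD.Scid mice. Per the labels' protocols, islets were cut by laser capture from methanol-fixed frozen sections stained with eosin, RNA was extracted on columns with DNase treatment, and the pooled RNA of 5 mice per array was amplified and labelled with biotin. The labels put 1 array in the untreated group, 3 arrays in the diabetogenic arm (days 3, 4 and 8 after transfer of T cells) and 4 arrays in the protected arm (days 3, 4, 5 and 8). The protected mice received the same T cells and 2 injections of an antibody against interferon-γ (IFN-γ). No 2 arrays share both arm and day. No diabetogenic array of day 5 was analysed here, and per the submitters' design text those islets were too swollen to dissect.

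The deposited values are probe set intensities on a linear scale for 45101 probe sets, from the authors' table for the whole series. How the authors summarised and scaled them is not given in the sources used here. The values themselves reach down to about 1 and the array medians lie between 3.14 and 3.96. The number of arrays limits the precision of every comparison, since pooling 5 mice on an array leaves no spread between mice to measure.

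Values were analysed as log2(intensity + 2.155), the pseudocount being the median over arrays of each array's 25th percentile. All differences and folds below are on that scale, which understates the change of dim genes. Array medians on the log2 scale lay within 0.21 of each other, under the limit of 0.3 set for keeping the deposited scale, so no further normalization was applied. These medians lie at the dim end of the values, so the rule does not show that bright probe sets share a scale. The 99th percentile of intensity was 25.6 and 67.0 on the diabetogenic and protected arrays of day 4 and 94.9 on the untreated array. Probe sets were named from the platform annotation of 2016, in which 34958 probe sets carry 1 gene symbol, 932 carry several and 9211 carry none. Only those with 1 symbol were used. A probe set was tested if it was at or above its array's median on at least 2 of the 8 arrays. Where a gene had several such probe sets, which was so for 7310 genes, the 1 with the highest mean over the 8 arrays was taken, leaving 16396 genes.

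Tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend) and adjusted by the method of Benjamini and Hochberg, with 0.05 as the threshold. The diabetogenic and protected arms were compared over the 6 arrays of days 3, 4 and 8 with day as a block. Each arm was also compared with the untreated array in a fit of all 8 arrays, which assumes that the lone untreated array varies like the arrays of different days within an arm. The change per day and the difference in that change between arms were fitted over the 7 injected arrays. In the comparisons with untreated islets the spread is that between days within an arm. In the matched-day fit it is array noise and the change of the arm difference between days, and in the slope fits the scatter around a line. Each day is represented by 1 pool of mice per arm. A gene's own spread had 2 residual degrees of freedom in the matched-day fit, against 29.99 from the variance trend over all genes. Its SEs and p-values therefore rest mostly on the spread of genes of like level, not on the gene's own days. In the other fits the trend also outweighed the gene's own spread. For single days, genes differing by at least 2-fold were counted with no test.

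The 27 gene lists (490 genes, of which 425 had a probe set with 1 symbol and 400 were tested) were fixed before the data were examined, as were the comparisons and their alternatives. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. For single arrays a list's median was set against 10000 random lists of the same size matched on mean expression, as a description of those arrays. Genes named in the text are the 10 largest passing differences per direction with the same sign on every day (where fewer than 5 passed, the 5 largest whether or not they passed), the 2 to 4 largest members of each list described in detail, and a fixed set of interferon-response, T cell and beta cell genes. Exceptions are marked where they occur.

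Each fit was tested on simulated data in which 200 of the 16396 genes were changed. The comparison of the arms over matched days recovered 93% of genes changed by 2 on the log2 scale and 100% of those changed by 4, with 20 false calls, which is more than the threshold allows for. The comparison of the diabetogenic arm with the untreated array recovered 15% and 73% at those sizes, and that of the protected arm 19% and 75%, with 9 false calls each. The fit of the change per day recovered 51% of genes changing by 0.5 per day and 99% of those changing by 1 per day, with 11 false calls. The fit of the difference in slope recovered 6% and 32%, with 3 false calls. In a simulation with 1 shifted list, camera called that list and 0 others. The noise in all these simulations was independent between genes. In the data the estimated correlation was 0.877 within the GTPase list and 0.774 within the acinar list. The simulation therefore cannot show how often camera calls lists of correlated genes wrongly.

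Alternatives covered quantile, median and cyclic loess normalization, a smaller and a larger pseudocount (0.539 and 8.62), the filter on dim probe sets, the handling of several probe sets per gene, the variance model, the day block, the time scale, the set test and leaving out each array or day pair. Array quality weights, and the presence of spiked hybridisation controls as a covariate, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.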

Results

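Islets from NOD.Scid mice, an autoimmunity-prone strain that forms no mature T or B cells of its own, were profiled after transfer of BDC2.5 CD4 T cells, which carry a transgenic receptor for a beta cell antigen and cause diabetes. In the protected arm an antibody neutralising IFN-γ was given the day before and 2 days after the transfer, and per the submitters' design text those mice did not become diabetic. The 8 arrays comprised 1 of untreated islets, 3 of the diabetogenic arm (days 3, 4 and 8) and 4 of the protected arm (days 3, 4, 5 and 8). Each array held the pooled RNA of 5 mice, with no second array for any arm and day.

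The arrays differed in signal. Probe sets at 8 or more times the array median made up 4.74% of the untreated array, 4.74% and 5.34% of the diabetogenic and protected arrays of day 3, and 3.85% of the protected array of day 5. The share was 0.850% and 2.23% for the diabetogenic and protected arrays of day 4, and 2.00% and 3.09% for those of day 8. Spiked hybridisation controls, bacterial and phage transcripts added at the hybridisation step, had a median intensity between 1.48 and 2.29 on the untreated array and both day 3 arrays and between 551 and 1712 on the 5 later arrays. The ratio of 3' to 5' probe sets of Actb, which rises when RNA is degraded or its copies are short, was 1.86 on the untreated array, 5.54 and 5.01 on the diabetogenic and protected arrays of day 3, 2.25 and 9.24 on those of day 4, 24.2 on the protected array of day 5, and 13.8 and 10.5 on the diabetogenic and protected arrays of day 8. For Gapdh it was 5.14 on the untreated array and, in the same order, 9.11 and 8.49 on day 3, 2.78 and 10.5 on day 4, 6.40 on day 5, and 19.0 and 10.8 on day 8. The 3' Actb probe set was dim on the untreated and diabetogenic day 4 arrays (12.4 and 20.5, against 43.4 to 168 on the others), so their low Actb ratios are uncertain. The arms of each matched day lay on the same side of the split in spiked controls, whereas the untreated array lay apart from all arrays of day 4 and later.

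**Figure D1:**
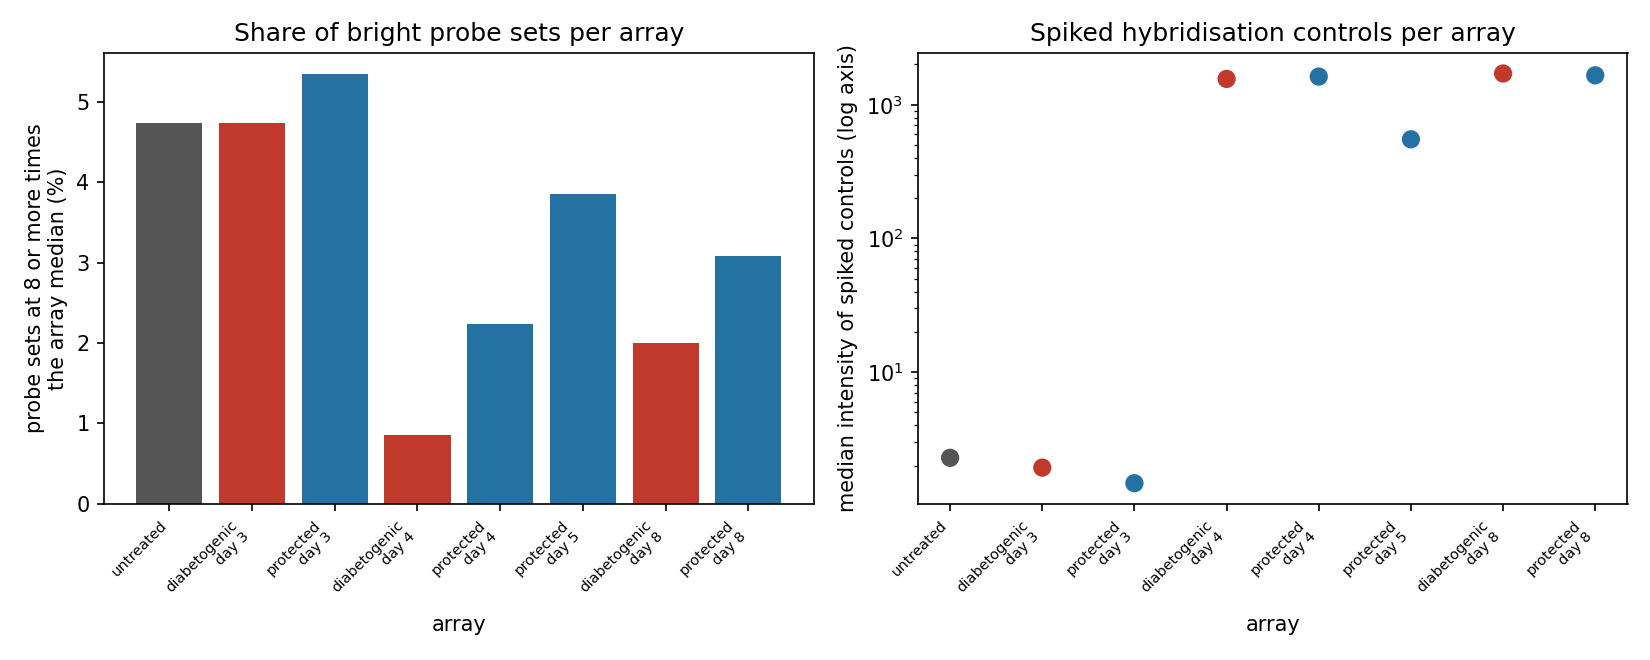
The left panel plots the percent of probe sets at 8 or more times the array median for each of the 8 arrays, and the right panel the median intensity of the spiked hybridisation controls on a log axis (grey, untreated; red, diabetogenic; blue, protected). The diabetogenic array of day 4 has the smallest share, 0.850%, and the untreated and day 3 arrays show spiked controls at 1.48 to 2.29 against 551 to 1712 on the others.

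The first comparison asked what differed in T cell-infiltrated islets when IFN-γ was neutralised, with the arms paired by day. None of the arms received a control antibody, so an effect of neutralisation cannot be told apart from one of the antibody injections themselves. The largest difference was in Ccl24, a chemokine that attracts eosinophils, which was 22.9-fold lower in diabetogenic than in protected islets (log2 difference −4.51 ± 0.49 (SE), 3 day pairs, adjusted p = 2.42e-06). Its intensity was 118, 476 and 56.0 on the protected arrays of days 3, 4 and 8, and 4.20, 10.8 and 1.26 on the diabetogenic ones, against 1.12 in untreated islets. In all, 15 genes were lower and 3 higher in diabetogenic islets, every one with the same sign on all 3 days. Among 16396 genes, 1471 had an unadjusted p under 0.05, where 819.8 would be expected with no difference.

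The next largest of the lower genes were Rnase2a, an eosinophil-type ribonuclease (16.2-fold, −4.02 ± 0.57), Chil3, a chitinase-like protein secreted by macrophages (14.7-fold, −3.88 ± 0.54), and Reg3b, a secreted lectin of the exocrine pancreas (9.53-fold, −3.25 ± 0.51). They were followed by the chemokine gene Ccl9 (−2.89 ± 0.46), the metalloproteinase inhibitor gene Timp1 (−2.87 ± 0.47), Retnla, which encodes resistin-like alpha (−2.54 ± 0.40), Arg1, which encodes the arginine-degrading enzyme arginase (−2.22 ± 0.41), Hemk1 (−2.15 ± 0.44) and the fibronectin gene Fn1 (−2.10 ± 0.39). Adjusted p for these 9 genes ran from 0.000269 to 0.0328. Chil3 stood at 34.3, 352 and 140 on the protected arrays of days 3, 4 and 8 and at 2.75, 4.01 and 16.8 on the diabetogenic ones. The other 5 lower genes, named here after their values were seen except for the list member Cd163, were the haemoglobin scavenger receptor gene Cd163, Dab2, Rnpep, Ramp3 and Flrt3, with log2 differences from −1.89 to −1.60. The last 3 were mostly at the bottom of the scale on the diabetogenic arrays of days 3, 4 and 8. Rnpep stood there at 4.16, 1 and 1, Ramp3 at 1, 1 and 2.03, and Flrt3 at 1.30, 1.42 and 1. A second probe set gave 0.03 for Hemk1 and 0.28 for Fn1, so each of these differences rests on 1 probe set, and a second one of Reg3b gave −2.76. Those of Hemk1 and Fn1 were dim (mean intensity 5.35 and 3.45, against 29.4 and 19.6 for those used), which limits what they can show.

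Of the 3 genes higher in diabetogenic islets, Gbp6 (4.51-fold, 2.17 ± 0.45, adjusted p = 0.0383) encodes an interferon-induced guanylate-binding GTPase. Its intensity was 118, 24.5 and 30.8 on the diabetogenic arrays and 12.4, 3.33 and 12.2 on the protected ones, and its second probe set gave 1.02. Ccdc93 was 5.33-fold higher (2.41 ± 0.42, adjusted p = 0.00565), although its 3 other probe sets gave −0.63 to 0.17, and Ccdc18, named after its value was seen, differed by 1.58 ± 0.33 (adjusted p = 0.0400). Those 3 probe sets of Ccdc93 were dim, with mean intensities of 2.71 to 4.56 against 11.4 for the one used. Ccdc18 stood at 10.4, 8.12 and 6.83 on the diabetogenic arrays and at 1.49, 1.62 and 1 on the protected ones, below the median of each protected array. Cxcl9 (2.27 ± 0.54, adjusted p = 0.114), Ncoa4 (2.16 ± 0.57, adjusted p = 0.217) and Rab3il1 (1.82 ± 0.40, adjusted p = 0.0563) had the same sign on every day and did not pass. Other probe sets gave 0.51 for Cxcl9, −0.07 for Ncoa4 and −0.74 to 0.94 for Rab3il1. Those of Cxcl9 and Ncoa4 were dimmer than the ones used (mean intensity 6.60 and 3.89, against 41.6 and 36.3). Cxcl9, an IFN-γ-induced ligand of the T cell chemokine receptor CXCR3, stood at 127, 31.9 and 89.3 on the diabetogenic arrays and at 8.60, 3.50 and 56.8 on the protected ones.

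**Figure D2:**
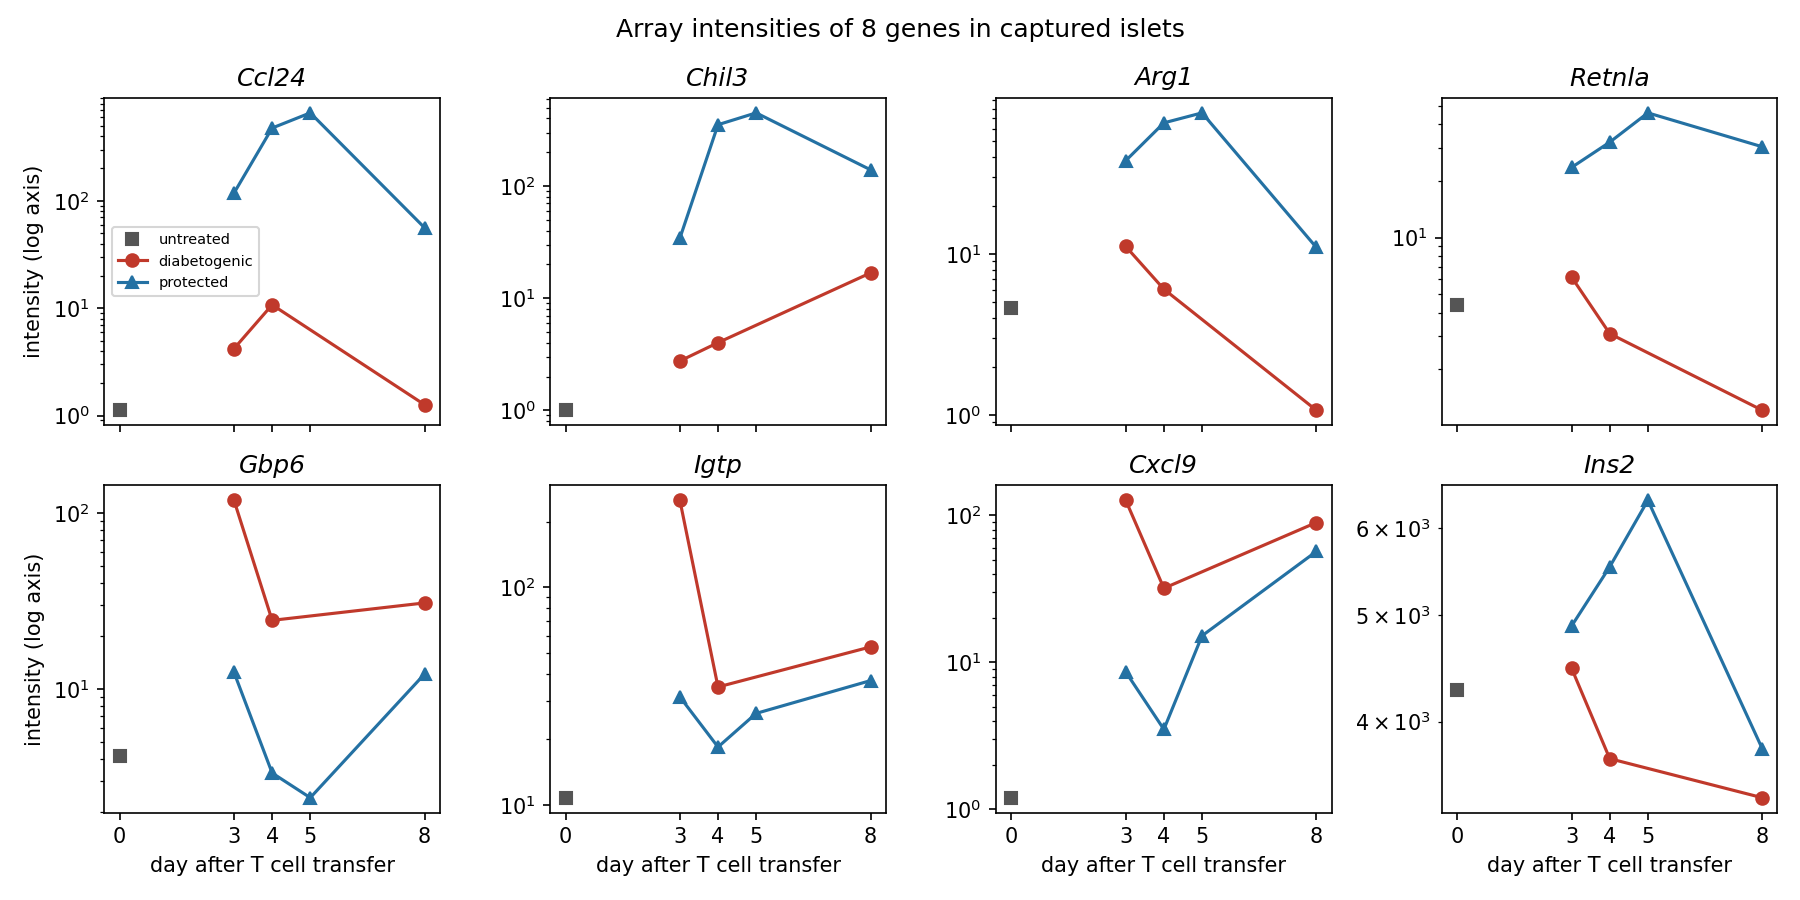
Array intensity (log axis) of 8 genes against the day after T cell transfer, with 1 point per array (grey square, untreated; red circles, diabetogenic; blue triangles, protected) and no error bars because each point is 1 pool of 5 mice. Ccl24, Chil3, Arg1 and Retnla lie higher on every protected array than on the diabetogenic array of the same day, Gbp6, Igtp and Cxcl9 lie lower, and Ins2 stays between 3409 and 6359 throughout.

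The other genes followed throughout did not pass. Ifng, the transcript of the neutralised cytokine, stood at 43.8 and 27.6 on the diabetogenic and protected arrays of day 3, 17.4 and 15.9 on those of day 4 and 3.80 and 7.62 on those of day 8, against 1.92 in untreated islets (0.01 ± 0.42 over the 3 days). The chemokine gene Cxcl10 stood at 71.8 and 10.3 on the diabetogenic and protected arrays of day 3 and between 2.17 and 6.14 on those of days 4 and 8 (0.87 ± 0.42). Cd274, which encodes the inhibitory ligand PD-L1, stood at 45.5 and 11.4 on day 3 (0.66 ± 0.40 over the 3 days). The differences were 0.74 ± 0.45 for the transcription factor gene Irf1, 0.85 ± 0.36 for Nos2, 0.36 ± 0.35 for Vcam1, −0.10 ± 0.34 for Ciita and −1.30 ± 0.39 for the T cell receptor component gene Cd3e. For Ins2, the brightest or nearly the brightest transcript on each array, it was −0.29 ± 4.56, an SE drawn mostly from the variance trend over all genes. The smallest adjusted p among all these genes was 0.344.

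The 18 calls rested on blocking by day, since 0 genes passed without the block, and 1, Ccl24, passed after quantile normalization or with the mean of all probe sets per gene, while median centring kept 17 of the 18 and cyclic loess 10. Leaving out the day 3, day 4 or day 8 pair gave 69, 33 and 40 genes, 59, 21 and 19 of them lower in diabetogenic islets, and 13, 9 and 14 were among the 18.

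Of the 27 gene lists, 2 were higher and 5 lower in diabetogenic islets by camera with its preset correlation, and 0 passed with an estimated correlation. All 10 tested GTPases of the GBP and IRG families, which IFN-γ induces in defence against intracellular pathogens, had a positive mean difference (list mean 1.12, adjusted p = 1.59e-09; adjusted p = 0.686 with an estimated correlation). 1 of them, Gbp6, passed over all genes and 5 passed adjusted over the list alone. Their median difference was 2.49 on day 3, 0.58 on day 4 and 0.02 on day 8, and without the day 3 pair the list mean was 0.44 (adjusted p = 0.0412). Igtp (1.42 ± 0.59), Iigp1 (1.41 ± 0.52) and Gbp2 (1.29 ± 0.64) did not pass over all genes. Gbp2 stood at 216 and 29.3 on the diabetogenic and protected arrays of day 3 and at 72.5 and 83.1 on those of day 8.

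The type I interferon-stimulated genes also passed as higher in diabetogenic islets (21 tested, 15 positive, mean 0.20, adjusted p = 0.0386; adjusted p = 0.820 with an estimated correlation), with 0 members passing, over all genes or adjusted over the list alone. Their median was 1.16 on day 3 and 0.03 and 0.11 on days 4 and 8, and without the day 3 pair the list mean was −0.22. The largest members were Rsad2 (0.71 ± 0.40), Ifit2 (0.69 ± 0.35), Oasl2 (0.64 ± 0.35) and Usp18 (−0.62 ± 0.40), none passing. MHC class I processing genes, 11 of 13 of them positive, had a median of 0.84 on day 3 and −0.37 and 0.05 on days 4 and 8 and did not pass (adjusted p = 0.189). They passed when the day 4 pair was left out (mean 0.46, adjusted p = 0.000801) and with quantile normalization (mean 0.30, adjusted p = 0.0455), and without the day 3 pair their mean turned from 0.17 to −0.19. The immunoproteasome genes Psmb8 (0.80 ± 0.44) and Psmb9 (0.59 ± 0.45) stood at 70.6 and 41.6 on the diabetogenic array of day 3 and at 28.6 and 12.9 on the protected one. MHC class II genes did not pass (adjusted p = 0.473, 11 of 13 negative), with H2-Aa at −1.06 ± 1.91 and Cd86 at −0.90 ± 0.39. Their median was 0.05 on day 3, −0.83 on day 4 and 0.08 on day 8, and without the day 4 pair the list mean was −0.003.

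Markers of pancreatic acinar cells, the enzyme-secreting cells around the islets, were lower in diabetogenic islets (22 of 23 negative, mean −1.44, adjusted p = 8.04e-12; adjusted p = 0.763 with an estimated correlation). 0 passed over all genes and 15 passed adjusted over the list alone. Their median was 0.20 on day 3, −2.92 on day 4 and −2.16 on day 8. The elastase gene Cela1 stood at 298 and 267 on the diabetogenic and protected arrays of day 3, 5.08 and 298 on those of day 4, and 5.02 and 36.5 on those of day 8 (−2.55 ± 0.72). The other large members were the trypsin gene Prss2 (−2.37 ± 1.08), Sycn (−2.30 ± 0.71) and Ctrl (−2.30 ± 0.99). The Reg family of secreted lectins, also made by acinar cells, was lower too (6 of 6 negative, mean −1.50, adjusted p = 1.31e-06; adjusted p = 0.686 with an estimated correlation). Reg3b passed over all genes and 4 members passed adjusted over the list alone, with Reg1 at −2.21 ± 0.54, Reg2 at −2.03 ± 0.49 and Reg3a at −0.99 ± 0.37. Its median was −0.24, −2.83 and −1.48 on days 3, 4 and 8. Without the day 4 pair the mean was −0.77 for the acinar list and −0.93 for the Reg family, and without the day 3 pair −2.22 and −2.08. On days 4 and 8 the diabetogenic arrays also had the smaller shares of bright probe sets, 0.850% against 2.23% and 2.00% against 3.09%, and the Actb ratios were 2.25 against 9.24 and 13.8 against 10.5. The Gapdh ratios were 2.78 against 10.5 and 19.0 against 10.8.

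Beta cell genes were lower in diabetogenic islets (23 of 24 negative, mean −0.62, adjusted p = 0.00160; adjusted p = 0.686 with an estimated correlation), with 0 members passing over all genes or adjusted over the list alone, and the list no longer passed without the day 8 pair (mean −0.55, adjusted p = 0.223). The largest were Ero1b, an oxidase of insulin folding (−1.87 ± 0.67), the amylin gene Iapp (−1.33 ± 1.68), Trpm5 (−1.21 ± 0.43) and the granule protein gene Chgb (−1.07 ± 1.17). The list's median was −0.23 on day 3 (percentile 0.41 of matched random lists), −0.72 on day 4 (percentile 69.0) and −0.77 on day 8 (percentile 4.00), so genes of like level lay as low on the day 4 pair. Ero1b stood at 309 and 462 on the diabetogenic and protected arrays of day 3, 6.79 and 77.5 on those of day 4 and 18.0 and 72.5 on those of day 8. Iapp and Chgb rested on day 4, where the diabetogenic array had 0.850% bright probe sets. Their differences on that day were −3.49 and −3.30.

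Stromal and matrix genes were lower in diabetogenic islets (13 of 16 negative, mean −0.64, adjusted p = 0.00180; adjusted p = 0.686 with an estimated correlation), Timp1 and Fn1 passing over all genes and 3 members adjusted over the list alone. Acta2 (−1.45 ± 0.44) and the collagen gene Col1a2 (−0.92 ± 0.55) did not pass over all genes. The list's median was −0.31 on day 3 (percentile 0.11 of matched random lists), −0.18 on day 4 (percentile 92.15) and −0.93 on day 8 (percentile 0.83). On day 4, most random lists of like level therefore lay lower. Dendritic cell markers were lower as well (9 of 11 negative, mean −0.46, adjusted p = 0.0404; adjusted p = 0.686 with an estimated correlation), a call lost without the day 3 pair (mean −0.60, adjusted p = 0.0674) or the day 8 pair (mean −0.33, adjusted p = 0.107) and with the mean of probe sets (mean −0.34, adjusted p = 0.0731). 2 members passed adjusted over the list alone. Itgax stood at 1.16 and 4.32 on the diabetogenic arrays of days 4 and 8 and at 9.53 and 30.2 on the protected ones (−1.65 ± 0.39), and Fscn1 (−1.28 ± 0.46), Cd209a (−0.81 ± 0.38) and Batf3 (−0.76 ± 0.32) did not pass over all genes.

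The remaining 20 lists did not pass, with adjusted p from 0.0512 to 0.975. Among the chemokines, 9 of 24 were positive and 15 negative (adjusted p = 0.473), Ccl9 passing and Ccl17 (−2.16 ± 1.56) and Ccl8 (−1.77 ± 0.42) not. Macrophage and monocyte markers were negative for 20 of 27 (adjusted p = 0.0774), with Cd163 passing, and passed when the day 8 pair was left out (adjusted p = 0.00681) and with the mean of probe sets (adjusted p = 0.0384). They did not pass without the day 4 pair (mean −0.10, adjusted p = 0.902), without the day 3 pair (adjusted p = 0.325) or with quantile normalization (adjusted p = 0.350). Csf1r (−1.29 ± 1.28), Lyz1 (−1.08 ± 0.98) and Fcgr3 (−0.98 ± 0.42) did not pass. T cell markers were negative for 9 of 13 (adjusted p = 0.920), with Cd3e at −1.30, Cd247 at 0.51, Thy1 at −0.48 and Ubash3a at 0.27. T cell effector genes were positive for 13 of 21 (adjusted p = 0.193), with Il12rb2 at 1.05, Gzmk at 0.82, Tnf at 0.79 and Il4 at −0.71. Inhibitory and regulatory molecules were positive for 11 of 20 (adjusted p = 0.713). Arg1 passed, and Il18bp, which encodes a decoy for interleukin-18, was at 1.34 ± 0.44.

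**Figure D3:**
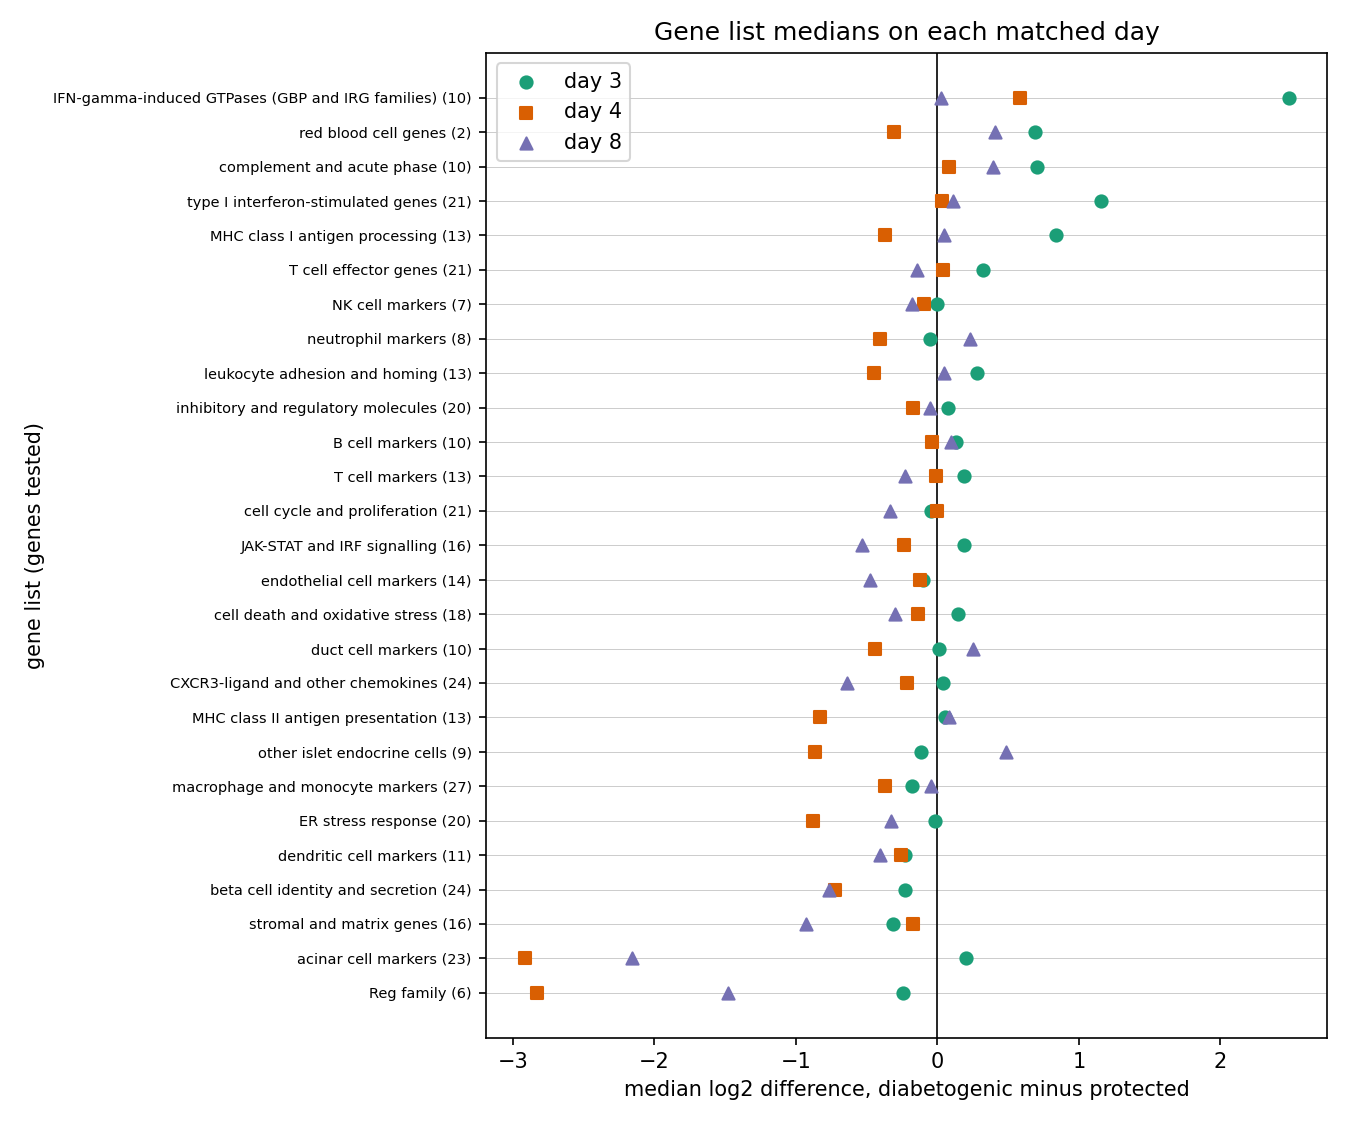
Median log2 difference, diabetogenic minus protected, of each of the 27 gene lists on days 3 (green circles), 4 (orange squares) and 8 (purple triangles), with the number of genes tested in parentheses and lists ordered by their mean over the 3 days. The IFN-γ-induced GTPases lie at 2.49 on day 3 and 0.02 on day 8, and the acinar markers at 0.20 on day 3 and −2.92 on day 4.

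Day by day, with 1 array per arm and no test, 303 genes differed by at least 2-fold between the arms on day 3, 220 of them higher in diabetogenic islets. On day 4 it was 3256 genes, 947 higher, and on day 8 it was 3755, 1475 higher. The SD of the difference over all genes was 0.38 on day 3, 0.82 on day 4 and 0.84 on day 8, and its median was −0.02, −0.13 and −0.10. All 10 tested GTPases and 11 of 21 type I interferon-stimulated genes were at least 2-fold higher in diabetogenic islets on day 3. With the pseudocount raised to 8.62, 79, 893 and 734 genes differed by at least 2-fold on the 3 days, and with 0.539 it was 851, 5372 and 6001.

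The next comparisons set each arm against untreated islets, to ask what T cell transfer did with and without IFN-γ. On day 3, where all arrays lacked spiked controls, interferon-response and antigen-presentation genes were the furthest above the untreated array in the diabetogenic arm, and MHC class II genes and macrophage markers in the protected arm. RNA quality may still differ here: the Actb ratio was 5.54 and 5.01 on the diabetogenic and protected arrays against 1.86 untreated, and the Gapdh ratio 9.11 and 8.49 against 5.14. The median of the 10 GTPases was 3.04 above untreated in the diabetogenic arm and 0.80 in the protected arm, each above all of 10000 matched random lists. For MHC class II genes the medians were 1.94 and 2.08, for MHC class I genes 1.82 and 1.13, for type I interferon-stimulated genes 1.67 and 0.34, and for macrophage markers 0.70 and 1.16. T cell markers lay at 0.20 and −0.15 and beta cell genes at −0.35 and −0.02. On day 3, 662 genes differed by at least 2-fold from untreated in the diabetogenic arm and 537 in the protected arm. These counts were 1568 and 1319 with a pseudocount of 0.539 and 183 and 156 with 8.62.

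On later days macrophage and MHC class II genes stayed above untreated and beta cell genes lay below it, again with no test. Spiked controls separated these arrays from the untreated one, and the Actb ratio was 2.25 on the diabetogenic array of day 4 and 9.24 to 24.2 on the others, against 1.86. The Gapdh ratio was 2.78 on that array and 6.40 to 19.0 on the others, against 5.14. The median of macrophage markers was 0.31 and 1.59 on the diabetogenic arrays of days 4 and 8 and 0.93, 2.22 and 1.47 on the protected arrays of days 4, 5 and 8. MHC class II genes lay at 0.25 and 1.79 in the diabetogenic arm and at 1.20, 2.55 and 2.46 in the protected arm. Beta cell genes lay at −3.66 and −3.86 in the diabetogenic arm and −2.71, −1.72 and −2.56 in the protected arm. The glucose transporter gene Slc2a2 stood at 161 in untreated islets, 73.7 and 75.8 on the diabetogenic and protected arrays of day 3, and between 1.76 and 11.7 afterwards. Genes differing by at least 2-fold from untreated numbered 5874 and 6058 on the diabetogenic arrays of days 4 and 8 and 4992, 3243 and 4026 on the protected arrays of days 4, 5 and 8. With a pseudocount of 8.62 they were 2770 and 2510, and 2122, 1290 and 1719.

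Tested over all arrays with limma, 0 genes differed between diabetogenic and untreated islets (450 at an unadjusted p under 0.05) and 0 between protected and untreated islets (371), with 819.8 expected by chance. The chemokine gene Ccl17 came closest, 295-fold higher in protected islets (8.20 ± 1.24, adjusted p = 0.0855), with an intensity of 3.00 in untreated islets, 559, 2417, 3667 and 1070 on the protected arrays and 132, 328 and 362 on the diabetogenic ones (5.62 ± 1.28, adjusted p = 0.894). It was followed in the protected arm by Ccl24 (6.05 ± 1.31), Chil3 (5.75 ± 1.31), the transglutaminase gene Tgm2 (5.68 ± 1.18) and Clec7a, a fungal-glucan receptor of myeloid cells (5.38). In the diabetogenic arm the next were Cxcl9 (4.46 ± 1.21), Clec7a (4.19 ± 1.29), Tgm2 (3.88 ± 1.22) and Gbp2 (3.74 ± 1.20). Among the lowest were Hadh, a fatty acid oxidation enzyme that is high in beta cells (−5.27 ± 2.03 diabetogenic, −3.80 ± 1.97 protected), and Slc2a2 (−3.76 ± 1.47 and −3.26 ± 1.42). Peg3, Cltrn and Scg2 completed the lowest 5 of the diabetogenic arm (−4.19 to −3.98), and the zinc transporter gene Slc30a8, Dnajb9 and Sphkap those of the protected arm (−3.36 to −3.22). None of these passed. For each arm the number at an unadjusted p under 0.05 rose above 819.8 when that arm's day 3 array was left out, so its shortfall depends on that array. In simulated data these 2 tests recovered 15% and 19% of changes of 2 on the log2 scale and 73% and 75% of changes of 4.

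The last comparisons asked how expression changed with day after transfer and whether that change differed between the arms. The 5 steepest upward slopes were those of Col1a2 at 0.91 ± 0.18 per day on the log2 scale, Sod3 at 0.86 ± 0.15, Col6a2 at 0.85 ± 0.16, Bgn at 0.84 ± 0.20 and Col6a1 at 0.72 ± 0.14. Col6a2 stood at 7.37 and 7.58 on the diabetogenic and protected arrays of day 3 and 142 and 216 on those of day 8. The steepest downward slopes were those of the prohormone-processing gene Cpe (−0.84 ± 0.23), Scg5 (−0.71 ± 0.25), Cela1 (−0.69 ± 0.25), Scg2 (−0.68 ± 0.31) and Mrfap1 (−0.64 ± 0.25). With limma 0 genes passed (1475 at an unadjusted p under 0.05; smallest adjusted p = 0.346). The day 3 arrays are also those without spiked controls, and with that split as a covariate 7 genes passed, all upward, while without the diabetogenic array of day 4 it was also 7.

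For the difference in slope 0 genes passed (327 at an unadjusted p under 0.05; smallest adjusted p = 0.99996). The largest positive differences, diabetogenic minus protected, were in the integrin gene Itgb8 (1.10 ± 0.21 per day), Ncoa4 (1.07 ± 0.29), Ube3a (0.81 ± 0.29), Cryba4 (0.74 ± 0.21) and Tasor (0.71 ± 0.22). The largest negative ones were in Iigp1 (−0.88 ± 0.33), Fbxw9 (−0.73 ± 0.26), Myo1g (−0.71 ± 0.31), Limd1 (−0.66 ± 0.29) and Inhbc (−0.63 ± 0.26). On the diabetogenic array of day 8 Itgb8 stood at 70.2, Ncoa4 at 244 and Ube3a at 113, each against 15.8 or less on all other injected arrays. Without that array 3 genes passed, and the differences were 0.27 for Itgb8, −0.96 for Ncoa4, −0.59 for Ube3a, −0.065 for Tasor and 0.75 for Cryba4.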

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

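The tests in this part were chosen after the results they concern had been seen. Spiked hybridisation controls, which are not among the genes compared, were bright on the 5 arrays of day 4 and later, with median intensities of 1559 on the diabetogenic and 1624 on the protected array of day 4, 551 on the protected array of day 5, and 1712 on the diabetogenic and 1659 on the protected array of day 8. On the untreated array the median was 2.29, and on the day 3 arrays 1.93 and 1.48. The arrays therefore fall into 2 sets by these controls, and every comparison of untreated or day 3 islets with later ones crosses them. The values do not show why the controls differ or whether the sets were hybridised separately.

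The fall of beta cell genes relative to untreated islets is the pattern this split concerns most. On the protected array of day 8 the list's median was −2.56, below every random list matched on the level in the 3 arrays without spiked controls, and the same held on days 4 and 5, which argues against a general weakening of signal as the whole cause. The 2 sets of arrays do not overlap, with a gap of −1.37 between the highest later array and the lowest early one, so the fall cannot be told apart from the split in spiked controls. A lower share of beta cells in the captured tissue also remains open. Iapp was 0.75 or more above untreated on all 3 protected arrays of days 4 to 8. Ins2 lay at 0.37, 0.57 and −0.18 there, against list medians of −2.71, −1.72 and −2.56. It was within 2-fold of the brightest transcript of every array, spiked controls left aside. The spiked Cre control read 9618 to 10576 on the arrays of day 4 and later, above Ins2, but was not bright on the untreated array. These are 2 genes of a list of 24, of which 17 or more were at least 2-fold lower on each of these 3 arrays. A loss of expression within beta cells under T cell attack and the differences in RNA quality between arrays were not tested as causes.

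Iigp1, an IFN-γ-induced GTPase, differed between the arms in opposite directions, by 3.37 on day 3 and −1.18 on day 8 (diabetogenic minus protected). It was the 1 gene among 70 examined with at least 1 on the log2 scale in each direction. The contrast of day 3 with day 8 was not tested by itself, and Iigp1 did not pass in the fit of the difference in slope.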

How the results depend on the processing

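The array quality weights, the covariate for spiked controls and the emphasis on the day 4 arrays were chosen after the data were seen. No paired analysis by replicate number was possible because no 2 arrays share arm and day, and day served as the block. Of the 18 genes differing between the arms, Ccl24 passed under every setting that kept the day block, and the number passing ranged widely. It was 1 with quantile normalization, 1 with the mean of probe sets, 8 with the larger pseudocount, 10 with no filter, 11 without the variance trend, 32 with a filter on the mean and 31 with array quality weights. By limma it was 0 without the day block (272 at an unadjusted p under 0.05), 0 with all 7 injected arrays and no block (539) and 0 with day as a number (651), and 33 to 69 when a day pair was left out, highest without day 3. Without the block the spread between days enters the error. For the other settings the cause was not tested. All 18 were among the calls with the smaller pseudocount, the filter on the mean, the robust trend and the weights. The protected arm against untreated gave 1 gene with quantile normalization and 1 with every probe set, and 0 to 2 when an array was left out (1 without the protected array of day 3, 2 without the diabetogenic array of day 4), and the diabetogenic arm gave 0 throughout. The change with day gave 13 genes with cyclic loess, 2 without the variance trend, 7 with the covariate for spiked controls and 0 to 7 when an array was left out, 7 without the diabetogenic array of day 4. The difference in slope gave 0 to 3 when an array was left out, 3 without the diabetogenic array of day 8. Of the 27 lists, 7 of which passed at the settings chosen, 0 passed with an estimated correlation, 0 with fry for direction and 0 with fry for mixed change, and 6 to 10 under the other settings tried for lists, with some gained and some lost. By direction, the genes differing between the arms were 8 higher and 8 lower with cyclic loess, and 21 higher and 19 lower without the day 8 pair, against 3 and 15.

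The 2-fold counts between the arms were 851, 5372 and 6001 on days 3, 4 and 8 with the smaller pseudocount and 79, 893 and 734 with the larger. Against untreated, the smaller pseudocount gave 1568 and 1319 on the diabetogenic and protected arrays of day 3 and 4976 on the protected array of day 5. The larger one gave 183 and 156 on day 3, 2770 and 2122 on day 4, 1290 on day 5 and 2510 and 1719 on day 8, because it damps differences between dim probe sets, which limit what these arrays can show.

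Some directions turned. Ifng was −0.037 with median centring, −0.042 with the smaller pseudocount and −0.23 with all 7 injected arrays, whether unblocked or with day as a number. With cyclic loess Ins2 was 1.36, H2-Aa 0.23 and Chgb 0.073. With the mean of probe sets Ciita was 0.064 and Ubash3a −0.15. With a day pair left out, Ifng ran from −0.30 to 0.37, Ciita from −0.27 to 0.081, Lyz1 from −1.65 to 0.011, Chgb from −1.74 to 0.046 and the mean of the type I interferon-stimulated genes from −0.22 to 0.43. The sign turned without day 3 for that list, without day 3 or day 4 for Ifng, and without day 4 for the other genes. The slope of Scg2 was 0.19 with the covariate for spiked controls. With an array left out, slope differences ran from −0.96 to 1.41 for Ncoa4, −0.59 to 1.04 for Ube3a, −0.065 to 0.84 for Tasor, −0.95 to 0.23 for Fbxw9 and −0.90 to 0.94 for Inhbc. Their signs turned without the diabetogenic array of day 8, and for Inhbc also without the protected array of day 8. Of 2045 values of named genes under alternatives, 1886 kept direction and side of the threshold, 88 lost the threshold and 50 gained it. Only genes that passed in the matched-day fit could lose it, since the other fits gave 0 calls. Most of the 2045 values belong to genes that did not pass, so the share kept says little about the calls. Of 189 list values, 148 kept both, 18 lost the threshold, 9 gained it and 14 changed sign, all but 1 of these in lists that did not pass. The 18 losses could fall only among the 7 lists that passed. The mean of neutrophil markers was 0.010 with quantile normalization and 0.038 with the mean of probe sets, and that of adhesion and homing genes 0.089 with the mean of probe sets. With a day pair left out, list means ran from −0.19 to 0.46 for MHC class I genes, −0.042 to 0.19 for T cell effector genes, −0.10 to 0.022 for inhibitory molecules, −0.089 to 0.087 for neutrophil, −0.031 to 0.085 for NK cell and −0.12 to 0.00045 for B cell markers, −0.67 to 0.043 for other endocrine genes and −0.17 to 0.12 for adhesion and homing genes.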

Other observations

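The tests in this part were chosen after the results had been seen, except the counts over other splits of the arrays, which were set before. Complement and acute phase genes, a list that did not pass over matched days (adjusted p = 0.0774), had a median of 0.70 higher in diabetogenic than in protected islets on day 3, above every matched random list, and 0.39 on day 8, with 0.08 on day 4. It passed with quantile normalization (adjusted p = 0.0397) and without the day 4 pair (adjusted p = 0.00111), and its mean of 0.25 was 0.12 without the day 3 or the day 8 pair. ER stress genes, many of them abundant in beta cells, had medians of −0.02, −0.88 and −0.33 on days 3, 4 and 8, inside the range of matched random lists (percentiles 75.1, 38.9 and 73.5). They did not pass (adjusted p = 0.0512), nor without the day 4 pair (mean −0.15, adjusted p = 0.482), and passed with quantile normalization (adjusted p = 0.0455), with the mean of probe sets (adjusted p = 0.00181) and without the day 3 pair (adjusted p = 0.0202). Cell cycle genes lay 0.38 above untreated islets on the protected array of day 5, with 8 of 21 at least 2-fold higher, and 0.46 above on that of day 8, with 5 of 21. On the diabetogenic array of day 8 they lay 0.15 above, with 4 of 21, and on the day 4 arrays −0.05 (diabetogenic) and −0.11 (protected) from untreated. Neutrophil, NK cell and B cell markers had medians no further than 0.15 from untreated on both day 3 arrays.

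The 15 genes lower in diabetogenic islets include Arg1, Chil3, Retnla, Ccl24, Cd163 and Fn1, which are known from macrophages activated through the interleukin-4 pathway. For 8 of the 15, among them Ccl24, Chil3 and Retnla, the weak diabetogenic array of day 4 is argued against as the whole cause, since they also passed when all genes were fitted without the day 4 pair, and it stays open for the other 7, whose differences were −2.22 to −1.60 over all days and −1.81 to −1.45 without day 4, with larger standard errors (at most 0.47), and no longer passed. More macrophages in protected islets were weighed as the whole cause. The macrophage list's median was −0.18 on day 3 and −0.05 on day 8 (standard errors 0.17 and 0.19). For the 15 genes it was −1.63 and −2.74 and, free of their selection, −1.60 on day 8 for 18 genes called from days 3 and 4 alone. The list thus differed less, which argues against this cause only if genes vary independently. These standard errors treat the list's 27 genes on 1 pair of arrays as independent. The estimated correlation within the list was 0.111, so they are too small. On day 4, which this test did not use, the list's median was −0.37 (standard error 0.29) against −3.02 for the 15 genes. There 10 of 27 macrophage markers were at least 2-fold lower and 0 higher, the list being at percentile 78.1 of matched random lists. A smaller increase stays open, the list being at percentile 2.13 of matched random lists on day 3. A hypothesis is that IFN-γ may hold back this state of macrophage activation: of 25 genes listed for it after the calls were known, the 19 not called had a median of −0.44 on day 3, below all matched random lists, which somewhat more macrophages could also give. On day 4 their median was −0.63, at percentile 2.42, and on day 8 it was −0.33, at percentile 21.6, which leaves day 8 open; a first form of this test asked for both days together and was not met, and it was parted by day, with random lists matched anew on the level in the 3 arrays without spiked controls, after its values were seen.

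Acinar markers were lower in diabetogenic than in protected islets on days 4 and 8 and not on day 3. A weaker signal of the diabetogenic arrays is argued against as the whole cause, since the list's median of −2.92 on day 4, like that on day 8, lay below every random list matched on level. Different amounts of exocrine tissue taken along with the islets remain possible: 19 and 15 of 23 genes were at least 2-fold lower on days 4 and 8, and the lower share, 65.2%, was too mixed to decide. On the protected array of day 4 the acinar median was 0.37 above untreated islets, and on that of day 5 it was −1.38. Regulation of acinar genes by IFN-γ stays open and untested.

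The 6 matched arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes, 3 of the splits, the real one included, gave at least the real 18, the highest other giving 26. Those 2 others put both day 3 arrays with 1 array of day 4, so that within the day block they set the diabetogenic day 4 array against the protected one. The 3 other splits with 1 array of each day on either side gave 0 genes. For lists, 5 splits gave at least the real 7, the highest other giving 9. Within the day block, each of those others sets the diabetogenic against the protected array of a single day, day 3 or day 4. The 3 other splits with 1 array of each day on either side gave 2, 1 and 3 lists. For the difference in slope the real count is 0, so each of the 35 splits of the 7 injected arrays gives at least as many and the count says nothing about chance. The highest other split gave 841, which points to a structure of the arrays whose cause was not tested.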
